A study of Varroa destructor with 12 samples.

How the data were processed

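RNA was measured in 12 libraries of whole adult Varroa destructor females, in 3 groups of 4: susceptible mites in acetone-coated vials (ATH-S), resistant mites in acetone-coated vials (AN-CR) and resistant mites alive after contact with coumaphos (tAN-CR). Per the labels' protocols, polyA RNA was made into stranded libraries and sequenced as read pairs. The submitters' processing notes list FastQC 0.11.5, STAR 2.5.0a and HTSeq, without a version for HTSeq and without saying what each was used for. The deposited table holds 1 whole-number count per gene and library, for 10260 genes, and per the file headers the deposited annotation is NCBI Annotation Release 100 of Vdes_3.0. The strand setting of the counting and its treatment of reads that fit several places are not given in the sources used here. Reads of genes that overlap on opposite strands (1875 genes) and of near-identical copies may therefore be shared, and values of such genes are uncertain. Of 110 genes named in the text, 22 overlap a gene on the other strand and 2 a gene on the same strand.

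Gene products and coordinates were taken from the deposited annotation, which holds all 10260 IDs. The RefSeq gene table at hand is of another assembly version, held 7229 of the IDs as symbols, and was not used for coordinates. Totals ran from 4115192 to 12920119 counts per library, and intervals or floors drawn from them cover counting error only. Pairs of libraries within each group were checked for being copies of one another, and none was.

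Counts were analysed with R 4.3.3. Genes were kept by edgeR 4.0.16's filterByExpr (minimum count 10, minimum total 15), which left 9272 genes with 99.977% of all counts and left out 988. Libraries were scaled by TMM, and levels are given as TMM-scaled counts scaled to a common library size (CPM), as mean ± SD of 4 libraries. The 3 comparisons were tested by edgeR's robust quasi-likelihood test in 1 fit of all 12 libraries with group as the only term, with Benjamini-Hochberg adjustment over the genes tested. A gene was called at an adjusted p under 0.05, and log2 fold changes are given ± SE. The common dispersion was 0.0414, a biological coefficient of variation of 20.3%.

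Gene lists were matched on product names by patterns fixed before the data were examined, as were the comparisons, the tests and the rule for naming genes. The 27 lists with at least 5 tested genes are cytochrome P450, P450 electron donors, glutathione S-transferase, carboxyl/cholinesterase, ABC transporter, solute carrier, cytosolic sulfotransferase, cholinergic synapse, cuticle protein, chitin, yolk, germline, cell cycle, cilium and sperm, muscle, neuron, digestive peptidase, lipid, heat shock, oxidative stress, immune, ribosomal, respiratory chain, proteasome, histone, hormone receptor and secreted. The UDP-glycosyltransferase pattern matched 0 genes and the transposon-derived pattern 3, too few to test. Lists were tested with camera of limma 3.58.1 on voom values with a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. Genes named are the 10 largest rises and falls among called genes of at least 2-fold, at least 2 CPM and no overlap between groups, or the 5 lowest p where fewer than 5 pass. They also include up to 3 called members per list and direction, all acetylcholinesterase and NADPH--cytochrome P450 reductase genes, and the 3 cytochrome P450 genes with the lowest p. Not every gene that the rule allows is printed.

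Alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile scaling, no filter, a filter of 5 CPM in 4 libraries, only the compared groups in the fit, a replicate block, leaving out each library in turn, and camera with an estimated correlation or fry for lists. Chosen after seeing the data were fits with the level of heat shock protein 83-like or of vitellogenin-6-like as a covariate, fits without the libraries extreme in either, and for the exposure a length correction and a fit without mitochondrial genes. The steps were tested on simulated data with known changes. Counts were drawn independently for each gene, without states shared by the genes of a library, so the rates may not hold for the real libraries. For AN-CR against ATH-S, edgeR recovered 23.9%, 71.6% and 90.9% of genes changed by 0.5, 1 and 2 on the log2 scale among 9235 genes, and 3.88% of its calls were wrong. For tAN-CR against ATH-S it recovered 17.9%, 76.1% and 90.9% among 9242 genes, with 3.91% wrong. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9. Raw reads and the labels' resistance assays were not analysed here.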

Results

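RNA was sequenced from whole adult females of Varroa destructor, the mite that parasitises honey bees, from 2 colonies in Greece that differ in their response to coumaphos. Coumaphos is an organophosphate acaricide, a class that acts on acetylcholinesterase, the enzyme that clears the transmitter acetylcholine. The ATH-S group was the susceptible population, from a colony left without chemical treatment for 19 years. The AN-CR group was the resistant population, from a colony where coumaphos had been the near-exclusive acaricide for 14 years. Both groups stayed for 20 h at 25 °C in vials coated with acetone. The tAN-CR group was the same resistant population, kept for 20 h in 12 mL vials coated with 500 µL of acetone holding 200 mg coumaphos per litre, and only living mites were collected. Each group had 4 libraries, described in the labels as biological replicates, each made from 10 to 20 females.

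The libraries held 4115192, 10928831, 9315368 and 10388477 gene counts in ATH-S replicates 1 to 4. The AN-CR libraries held 11970646, 11087101, 11543527 and 12920119, and the tAN-CR libraries 9952159, 8707457, 10704316 and 6047793. Of 10260 protein-coding genes, 9272 passed the filter on low counts. Mitochondrial genes made up 0.534% ± 0.034 of counts in ATH-S, 0.474% ± 0.050 in AN-CR and 0.928% ± 0.081 in tAN-CR (SD, n = 4 each). The share in tAN-CR exceeded that in AN-CR in every library (exact 2-sided permutation test, p = 0.0286, the smallest that 4 against 4 allow), and AN-CR and ATH-S did not pass the same test (p = 0.114). Pearson correlations of log2 CPM (counts scaled to a common library size) across genes were 0.941 to 0.983 within ATH-S, 0.958 to 0.989 within AN-CR and 0.966 to 0.987 within tAN-CR. Of the 12 libraries, 5 correlated best with a library of another group. These were ATH-S replicate 1 with AN-CR replicate 1 (r = 0.977), AN-CR replicates 3 and 4 with tAN-CR replicate 1 (0.988 and 0.9895), tAN-CR replicate 1 with AN-CR replicate 4 and tAN-CR replicate 3 with AN-CR replicate 2 (0.985).

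Libraries differed within groups in 2 abundant transcripts. Heat shock protein 83-like (LOC111244541), a cytosolic chaperone, stood at 12690, 7415, 3480 and 25930 CPM in ATH-S replicates 1 to 4, against 2135 to 3325 CPM in the AN-CR libraries. Vitellogenin-6-like (LOC111249976), a yolk protein precursor, stood at 53.6 CPM in ATH-S replicate 4 and 172 CPM in AN-CR replicate 1, against 2044 to 10740 CPM in the other libraries. This vitellogenin gene was singled out after its values were seen. A further vitellogenin-6-like gene (LOC111244790) went the other way, highest within its group in ATH-S replicate 4 (2024 CPM) and AN-CR replicate 1 (640 CPM). Vitellogenin-3-like (LOC111248912) stood at 143 CPM in ATH-S replicate 4 (others 116 to 1186) and 34.8 CPM in AN-CR replicate 1 (others 96.8 to 100). The vitellogenin covariate and the low-vitellogenin libraries below rest on LOC111249976 alone.

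**Figure D1:**
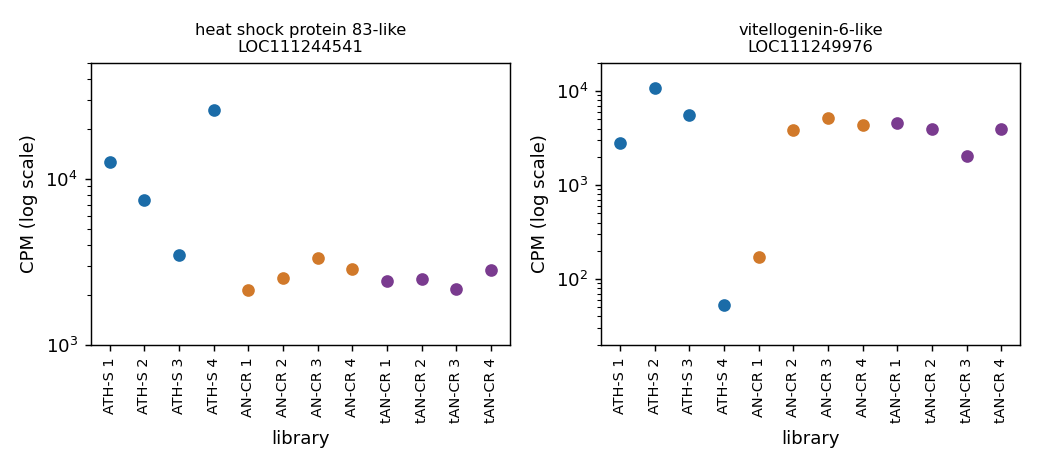
Level of heat shock protein 83-like and of vitellogenin-6-like in each of the 12 libraries, in CPM on log axes, with 1 dot per library coloured by group. Heat shock protein 83-like ranges from 3480 to 25930 CPM in ATH-S and from 2135 to 3325 CPM in AN-CR, and vitellogenin-6-like is lowest in ATH-S replicate 4 and AN-CR replicate 1.

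The comparison of AN-CR with ATH-S asks which transcripts differ between the resistant and the susceptible population without the acaricide. Cytochrome P450 4V2-like (LOC111248731), of a family of oxidases that metabolise foreign compounds, was at 404 ± 134 CPM in ATH-S and 109 ± 13.8 CPM in AN-CR (SD, n = 4 each), a log2 fold change of -1.89 ± 0.20 (SE; edgeR adjusted p = 0.00023). Of 11 genes with acetylcholinesterase in their product name, 4 fell in AN-CR and edgeR called 0 higher. The largest fall was in acetylcholinesterase-1-like (LOC111248568), at 69.4 ± 22.6 against 27.2 ± 4.80 CPM (-1.35 ± 0.21). Whether each of the 11 encodes the enzyme that coumaphos acts on was not tested. Apolipophorins-like (LOC111244169), a lipid carrier, fell from 8020 ± 2466 to 2670 ± 408 CPM (-1.59 ± 0.20). Heat shock protein 83-like fell from 12380 ± 9790 to 2715 ± 507 CPM (-2.19 ± 0.45, and -1.56 without ATH-S replicate 4).

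In all, 2299 of 9272 genes (24.8%) differed by edgeR's quasi-likelihood test, 1118 higher and 1181 lower in AN-CR. Changes of at least 2-fold were mostly falls, with 57 genes higher and 412 lower. The log2 CPM of the 2 groups did not overlap for 22.2% of genes, against 2.86% by chance. Under upper-quartile scaling 873 genes were higher and 1409 lower, so that the higher genes made up 38.3% of the calls against 48.6% with TMM scaling. That scaling moved the median log2 fold change of all genes by -0.05. With only the compared groups in the fit edgeR called 1542 genes, 665 higher and 877 lower. The count was 1359 without AN-CR replicate 2. It was 440 with the level of heat shock protein 83-like as a covariate and 3422 (1860 higher and 1562 lower) with that of vitellogenin-6-like, covariates added after the data were seen. Population and resistance cannot be told apart, because each phenotype comes from 1 colony.

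Among 23 tested cytochrome P450 genes, 1 rose and 7 fell, and the same counts came out adjusted over the list alone. Cytochrome P450 4c3-like (LOC111246379) rose from 13.6 ± 6.11 to 39.2 ± 13.8 CPM (1.56 ± 0.39, edgeR adjusted p = 0.0129). Probable cytochrome P450 49a1 (LOC111246534) fell by 1.55 ± 0.26, a second 4c3-like gene (LOC111246554) fell by 0.98 ± 0.25 and cytochrome P450 3A14-like (LOC111246682) fell by 0.75 ± 0.14 on the log2 scale. The list was lower as a set (camera adjusted p = 0.00674), with an adjusted p = 0.325 with an estimated correlation. The 4V2-like gene lies on scaffold NW_019211454.1 of Vdes_3.0 at positions 11028937 to 11030853 on the minus strand, as 1 exon. It sits inside the span of a gene on the plus strand (LOC111248725, 10985975 to 11048282) and overlaps 0 of that gene's exons. It was lower in all 8 fits that left out 1 library, and -1.49 ± 0.24 with heat shock protein 83-like as a covariate.

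Of 10 P450 electron donor genes, 1 rose and 4 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0741). The rise was NADPH--cytochrome P450 reductase-like (LOC111252141), which passes electrons to P450 enzymes, from 240 ± 61.7 to 359 ± 86.5 CPM (0.58 ± 0.20, edgeR adjusted p = 0.0461). Its groups overlapped in ATH-S replicate 1 and AN-CR replicate 3, and its call was lost without AN-CR replicate 1, 2 or 4 or ATH-S replicate 2 or 3, with an adjusted p of up to 0.117. Cytochrome b5-like (LOC111254515) fell from 147 ± 49.3 to 79.7 ± 10.8 CPM (-0.88 ± 0.20). The name pattern also took in cytochrome b561-like (LOC111251541), a membrane electron carrier outside the P450 system, which fell by 0.98 ± 0.15 on the log2 scale.

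Among 16 carboxyl/cholinesterase genes, 0 rose and 7 fell (1 and 8 adjusted over the list alone; 9 genes had an unadjusted p under 0.05). DESeq2 called 8 and limma-voom 7. The list was lower as a set (camera adjusted p = 0.00524; adjusted p = 0.325 with an estimated correlation). Cholinesterase-like LOC111250776 fell from 12.5 ± 4.72 to 2.998 ± 0.432 CPM (-2.07 ± 0.28, edgeR adjusted p = 0.000525). The other acetylcholinesterase genes that fell were LOC111254737 (-1.18 ± 0.23), LOC111251676 (-1.15 ± 0.27) and LOC111244098 (-0.97 ± 0.26). The last lost its call without AN-CR replicate 3 (adjusted p = 0.0513). Of the 11, edgeR called 0 higher, 6 had an unadjusted p under 0.05 in either direction and DESeq2 called 5. The 1 gene that rose adjusted over the list alone is among the 11, as all 4 positive changes of the list are. The other 7 did not pass, at -0.30 (LOC111246636 and LOC111247698), -0.07 (LOC111247592), 0.23 (LOC111251954), 0.43 (LOC111252992), 0.59 (LOC111243720) and 0.83 (LOC111251379). The sign of LOC111251954 turned without AN-CR replicate 1 (-0.06), and that of LOC111247592 without AN-CR replicate 2 (0.01).

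The cholinergic synapse list shares these genes named acetylcholinesterase. Of its 24 genes 0 rose and 8 fell (0 and 9 adjusted over the list alone; 11 had an unadjusted p under 0.05, and DESeq2 called 9). Its camera adjusted p was 0.011, with an adjusted p = 0.325 with an estimated correlation. Acetylcholine receptor subunit alpha-like 1 (LOC111252572), part of a ligand-gated channel, fell from 24.7 ± 7.53 to 8.15 ± 2.17 CPM (-1.61 ± 0.25).

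**Figure D2:**
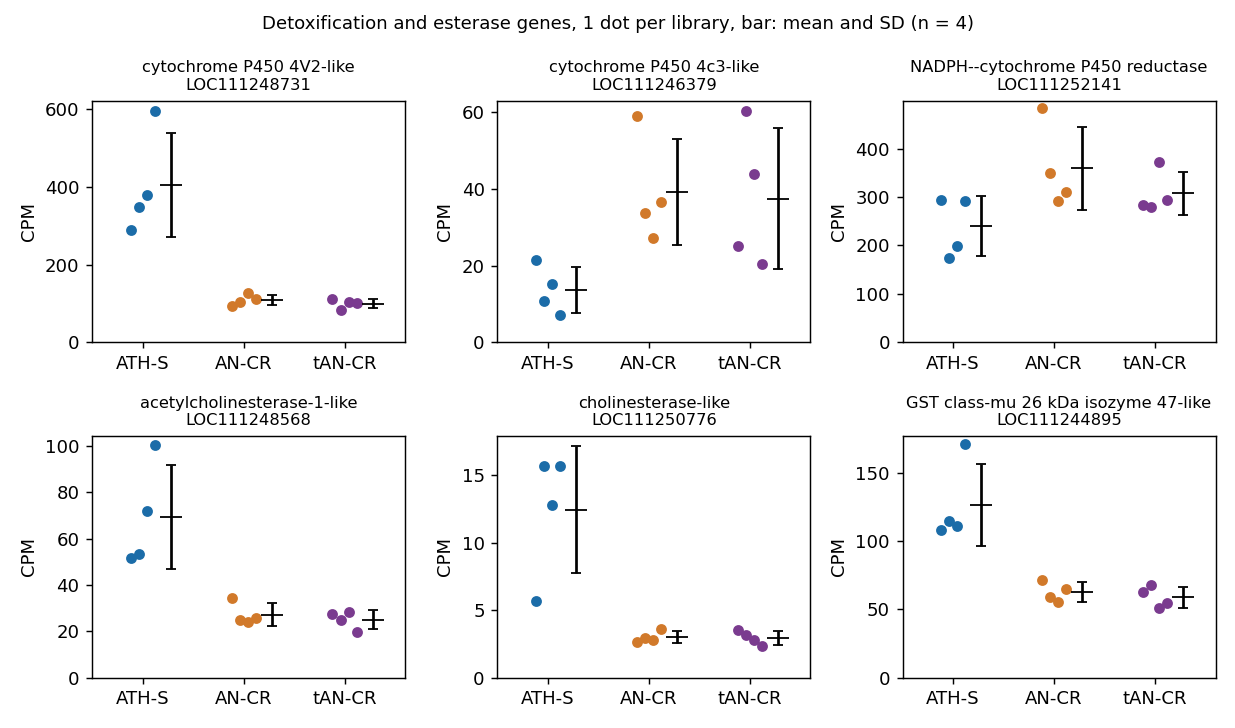
CPM of 6 detoxification and esterase genes in the 12 libraries, with 1 dot per library by group and the mean ± SD of 4 libraries beside them. Cytochrome P450 4V2-like falls from 404 ± 134 CPM in ATH-S to 109 ± 13.8 CPM in AN-CR, and the NADPH--cytochrome P450 reductase groups overlap.

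Among 11 glutathione S-transferases, conjugating enzymes, 2 rose and 5 fell, as they did adjusted over the list alone. The list's camera adjusted p was 0.0265, and 0.325 with an estimated correlation. With only the compared groups in the fit it was 0.0502. Glutathione S-transferase 4-like (LOC111253932) fell by 1.08 ± 0.23 and the class-mu isozyme LOC111244895 fell by 1.01 ± 0.15 on the log2 scale. Kappa 1-like (LOC111246365) rose from 56.7 ± 4.12 to 76.0 ± 5.28 CPM (0.42 ± 0.10). Of 11 cytosolic sulfotransferases, 1 rose and 4 fell, also over the list alone, and the list did not pass as a set (camera adjusted p = 0.144). Its median log2 fold change was 0.03 with TMM scaling and -0.01 with upper-quartile scaling, and its mean was -0.31. Sulfotransferase 1C2-like (LOC111247389) fell from 406 ± 162 to 134 ± 15.9 CPM (-1.60 ± 0.21) and amine sulfotransferase-like (LOC111246437) fell by 1.52 ± 0.18. The riser was heparan sulfate 2-O-sulfotransferase 1-like (LOC111253264, 0.54 ± 0.09), a Golgi enzyme that modifies proteoglycans and is not cytosolic.

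Of 35 ABC transporters, 2 rose and 5 fell (1 and 5 adjusted over the list alone; camera adjusted p = 0.379). Multidrug resistance-associated protein 4-like (LOC111254247), an export pump, fell from 194 ± 45.3 to 73.2 ± 6.53 CPM (-1.41 ± 0.18). A retinal-specific ABC transporter-like gene (LOC111253112) fell by 1.22 ± 0.26 on the log2 scale. ABC sub-family D member 1-like (LOC111244635), a peroxisomal transporter type, rose from 118 ± 21.0 to 201 ± 9.12 CPM (0.78 ± 0.14). Among 114 solute carrier and facilitator transporters, 7 rose and 34 fell (9 and 37 adjusted over the list alone; camera adjusted p = 0.00157; adjusted p = 0.325 with an estimated correlation). The steepest falls were in solute carrier family 22 member 8-like genes, at -2.78 ± 0.31 (LOC111253895) and -2.64 ± 0.35 (LOC111246739). Solute carrier family 25 member 35-like (LOC111250761) rose by 0.55 ± 0.13.

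In the chitin list 0 of 10 genes rose and 6 fell, as they did over the list alone and by DESeq2 (camera adjusted p = 0.00524; adjusted p = 0.155 with an estimated correlation). Chitinase-3-like protein 1 (LOC111250845) fell from 331 ± 61.1 to 124 ± 20.0 CPM (-1.42 ± 0.16), and the endochitinase-like gene LOC111250313 from 620 ± 120 to 265 ± 32.9 CPM (-1.22 ± 0.14). A further endochitinase-like gene (LOC111255436, -1.55 ± 0.41), whose groups overlapped in ATH-S replicate 2 and AN-CR replicate 1, lost its call without AN-CR replicate 2 (edgeR adjusted p = 0.0541). Of 51 cuticle protein genes 1 rose and 9 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.124). Cuticle protein 38-like (LOC111245573) fell from 4.53 ± 2.98 to 0.306 ± 0.286 CPM (-3.87 ± 0.64, and -4.55 to -3.58 over 7 fits that left out 1 library). It was not among the genes tested without ATH-S replicate 2. In AN-CR replicates 1 and 3 it stood at 0.08 CPM, under a floor of 3 counts per library (0.25 CPM). Cuticle protein-like LOC111254693 fell by 3.49 ± 0.69, though ATH-S replicate 4 (1.12 CPM) lay within the AN-CR libraries (1.10 to 2.07 CPM). Pupal cuticle protein G1A-like (LOC111247947) fell by 3.67 ± 0.86, and was -2.73 without ATH-S replicate 2. In ATH-S replicate 4 it stood at 0.12 CPM, below the AN-CR libraries (0.67 to 1.44 CPM). Cuticle protein 19.8-like (LOC111245255) rose from 0.716 ± 0.197 to 1.89 ± 0.570 CPM (1.36 ± 0.32).

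Among 45 digestive peptidases 1 rose and 6 fell (1 and 5 adjusted over the list alone; camera adjusted p = 0.0174; adjusted p = 0.155 with an estimated correlation). Chymotrypsin-like protease CTRL-1 (LOC111252338) fell from 17.3 ± 5.16 to 2.21 ± 1.12 CPM (-2.97 ± 0.34) and cathepsin L1-like (LOC111244088) from 602 ± 172 to 198 ± 51.9 CPM (-1.60 ± 0.20). Of 101 lipid metabolism genes 7 rose and 26 fell (9 and 30 adjusted over the list alone; camera adjusted p = 0.00307; adjusted p = 0.325 with an estimated correlation). Pancreatic triacylglycerol lipase-like (LOC111248832) fell by 1.71 ± 0.28, and calcium-independent phospholipase A2-gamma-like (LOC111243272) rose by 0.68 ± 0.16. Of 7 yolk and egg shell genes 0 rose and 3 fell, also over the list alone, with 4 at an unadjusted p under 0.05 and 3 called by DESeq2 (camera adjusted p = 0.417). Vitellogenin-6-like LOC111244790 fell from 1478 ± 456 to 404 ± 194 CPM (-1.87 ± 0.33). Vitellogenin-3-like (LOC111248912) stood at 508 ± 501 against 82.8 ± 32.1 CPM (-2.62 ± 0.71), and its call was lost without any 1 of the AN-CR libraries or ATH-S replicate 2 (edgeR adjusted p up to 0.0569), and was -1.77 without the latter.

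Of 56 heat shock and chaperone genes 4 rose and 14 fell (6 and 15 adjusted over the list alone; camera adjusted p = 0.124). Heat shock 70 kDa protein cognate 4-like (LOC111251692) stood at 10370 ± 9338 CPM in ATH-S and 2051 ± 536 CPM in AN-CR (-2.34 ± 0.51, and -1.58 without ATH-S replicate 4), and heat shock cognate 71 kDa protein-like (LOC111243059) at 2812 ± 1909 and 929 ± 206 CPM (-1.60 ± 0.39). In ATH-S replicate 3 both (2768 and 966 CPM) lay below the highest AN-CR library. Counts of near-identical heat shock 70 genes are uncertain, since reads that fit several copies may have been split or dropped. The log2 fold change of LOC111243059 was 0.245 with heat shock protein 83-like as a covariate. Heat shock 70 kDa protein-like LOC111252954 rose from 32.6 ± 12.96 to 61.6 ± 6.80 CPM (0.94 ± 0.21).

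Among 32 oxidative stress defence genes 0 rose and 8 fell, as over the list alone, with 15 at an unadjusted p under 0.05 and 12 called by DESeq2 (camera adjusted p = 0.011; adjusted p = 0.325 with an estimated correlation). Catalase-like (LOC111250508), which breaks down hydrogen peroxide, fell from 1366 ± 407 to 516 ± 96.9 CPM (-1.41 ± 0.20) and glutathione peroxidase-like (LOC111243815) fell by 1.16 ± 0.21. Of 48 immune genes 1 rose and 9 fell (1 and 8 adjusted over the list alone; camera adjusted p = 0.011; adjusted p = 0.325 with an estimated correlation). Toll-like receptor Tollo (LOC111247110) fell from 64.7 ± 27.6 to 9.59 ± 2.92 CPM (-2.76 ± 0.30). Lysozyme-like (LOC111248078), of a family that cleaves bacterial cell walls, fell from 124 ± 18.9 to 39.99 ± 1.53 CPM (-1.63 ± 0.12, edgeR adjusted p = 4.2e-05) and lysozyme C-like (LOC111248098) fell by 2.05 ± 0.30.

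In the mitochondrial respiratory chain list 0 of 70 genes rose and 22 fell, as over the list alone, with 32 at an unadjusted p under 0.05 and 30 called by DESeq2 (camera adjusted p = 1.23e-06; adjusted p = 0.325 with an estimated correlation). The list holds 65 nuclear and 5 mitochondrial genes and leaves out CYTB and the mitochondrial ND genes, whose product names its pattern does not match. Lower members were mitochondrially encoded COX1 (-0.60 ± 0.13) and ATP6 (-0.58 ± 0.14) and NADH dehydrogenase flavoprotein 1 (LOC111249888, -0.54 ± 0.12). Outside the list, and named after their values were seen, ND4 fell by 1.33 ± 0.20, ND5 by 1.18 ± 0.14, ND4L by 1.12 ± 0.23 and ND1 by 0.52 ± 0.11, each also called in all 8 fits that left out 1 library. Of 70 cytosolic ribosomal protein genes 0 rose and 5 fell (0 and 0 adjusted over the list alone, with 21 at an unadjusted p under 0.05 and 19 called by DESeq2). Their median log2 fold change was -0.20 (camera adjusted p = 1.79e-06; adjusted p = 0.562 with an estimated correlation). With upper-quartile scaling 19 of them fell.

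By camera with the preset correlation, the cell cycle and DNA replication list was the 1 list higher in AN-CR as a set. Of its 47 genes 13 rose and 2 fell (15 and 2 adjusted over the list alone). Its camera adjusted p was 0.00149, and 0.577 with an estimated correlation, and fry did not call it (adjusted p = 0.104). Fry called the cilium, axoneme and sperm list (adjusted p = 0.000553) and the hormone receptor list (0.0201) higher. DNA replication licensing factor mcm2-like (LOC111248841) stood at 64.8 ± 17.7 and 119 ± 50.0 CPM (0.87 ± 0.29) and kinesin-like protein KIF23 (LOC111245427), a motor of cell division, at 28.5 ± 8.54 and 50.8 ± 16.6 CPM (0.83 ± 0.26). Both calls were lost without AN-CR replicate 2, 3 or 4 or ATH-S replicate 1, 3 or 4, with an edgeR adjusted p of up to 0.149 and 0.118. In AN-CR replicate 1 they stood at 54.17 and 29.79 CPM, within the ATH-S libraries (50.15 to 87.15 and 17.35 to 36.82 CPM). The list's own call was lost with ATH-S replicates 1 and 4 left out together (camera adjusted p = 0.121), as were those of the cholinergic synapse (0.0685) and glutathione S-transferase (0.0657) lists.

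Of 23 cilium, axoneme and sperm genes 7 rose and 2 fell, as over the list alone (camera adjusted p = 0.145). Cilia- and flagella-associated protein 251-like (LOC111253068) rose by 1.76 ± 0.43 and intraflagellar transport protein 122 homolog (LOC111244971) rose by 0.92 ± 0.23. The pattern also matched spermidine synthase-like (LOC111247795, -0.70 ± 0.20), an enzyme of polyamine synthesis. Its groups overlapped in ATH-S replicate 2 and AN-CR replicate 1, and its call was lost without AN-CR replicate 2, 3 or 4 (edgeR adjusted p up to 0.0712). Of 5 germline genes 1 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.522), and the fall was in the RNA helicase vasa-like (LOC111250177, -0.50 ± 0.08). Of 18 genes in the histone list 3 rose and 4 fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.369). Its name pattern also took in a histone H4 transcription factor-like gene, which is not a histone. Histone H1-like (LOC111249131) fell by 1.90 ± 0.39 and histone H2A (LOC111254725) fell by 1.66 ± 0.43. For the first, ATH-S replicate 1 (29.6 CPM) lay below AN-CR replicate 4 (36.3 CPM). For H2A, ATH-S replicate 3 (16.96 CPM) lay below all AN-CR libraries (17.4 to 27.6 CPM). Histone copies may share reads, and polyA selection captures few replication-type histone transcripts.

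In 35 muscle genes 3 rose and 4 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.145). Paramyosin-like (LOC111250311) rose by 0.42 ± 0.09 and obscurin-like (LOC111244203) fell by 0.98 ± 0.21, with ATH-S replicate 1 (18.2 CPM) just under AN-CR replicate 4 (18.3 CPM). Among 86 neuron and synapse genes 3 rose and 17 fell, as over the list alone (camera adjusted p = 0.00219; adjusted p = 0.562 with an estimated correlation). Neuropeptide-like protein 31 (LOC111255289) fell from 33.0 ± 10.97 to 6.65 ± 1.27 CPM (-2.32 ± 0.25) and gamma-aminobutyric acid receptor alpha-like (LOC111246926) fell by 2.10 ± 0.41. The risers included gamma-aminobutyric acid receptor-associated protein-like (LOC111253864, 0.47 ± 0.11), of a family that acts in autophagy. Of 16 ecdysteroid and nuclear hormone receptor genes 1 rose and 0 fell, as over the list alone, with 5 at an unadjusted p under 0.05 and 1 called by DESeq2 (camera adjusted p = 0.256). The riser was steroid hormone receptor ERR1-like (LOC111251024, 0.46 ± 0.10). Of 35 proteasome genes 3 rose and 0 fell (0 and 0 adjusted over the list alone; 6 had an unadjusted p under 0.05 and DESeq2 called 3; camera adjusted p = 0.166).

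Of 68 secreted, salivary and venom-like genes 7 rose and 8 fell (6 and 7 adjusted over the list alone; camera adjusted p = 0.256). Venom protease-like (LOC111254963) rose from 2.85 ± 2.10 to 11.3 ± 3.15 CPM (2.14 ± 0.36) and mucin-5AC-like (LOC111249471) rose by 1.63 ± 0.28. A glycine-rich cell wall structural protein-like gene (LOC111252741) fell from 41.8 ± 16.4 to 8.68 ± 1.84 CPM (-2.28 ± 0.27) and mucin-17-like (LOC111252694) fell by 1.87 ± 0.34.

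The largest rises and falls included genes outside the lists. Uncharacterized LOC111242995 rose from 1.29 ± 0.861 to 6.37 ± 2.44 CPM (2.43 ± 0.46). Other uncharacterized genes that rose were LOC111254793 (1.66 ± 0.32), LOC111247071 (1.65 ± 0.27), LOC111248996 (1.29 ± 0.29) and LOC111244793 (1.26 ± 0.21). Ras-related protein Rap-2a-like (LOC111255205) rose by 1.24 ± 0.30. Chaoptin-like (LOC111247524, 1.45 ± 0.47) lost its call without AN-CR replicate 2, 3 or 4 or ATH-S replicate 1, 2 or 4 (edgeR adjusted p up to 0.11). Uncharacterized LOC111244763 stood at 2105 ± 2107 CPM in ATH-S and 26.5 ± 7.24 CPM in AN-CR (-6.31 ± 0.96, and -5.49 without ATH-S replicate 4). Inositol-3-phosphate synthase-like (LOC111255015), which makes inositol phosphate from glucose 6-phosphate, stood at 3364 ± 3212 and 312 ± 44.5 CPM (-3.43 ± 0.59, and -2.61 without ATH-S replicate 4). In ATH-S replicates 1 to 4 LOC111244763 stood at 2554, 861, 131 and 4874 CPM and LOC111255015 at 3518, 1441, 665 and 7830 CPM. Both ranked these libraries in the same order as heat shock protein 83-like. Whether their falls follow that uneven state was not tested. Falls were also seen in LOC111248074 (-5.60 ± 1.25, and -4.80 without ATH-S replicate 3), LOC111249382 (-3.81 ± 0.71), the nek3-like kinase LOC111246992 (-2.84 ± 0.50, and -2.21 without ATH-S replicate 4) and MFS-type transporter SLC18B1-like (LOC111248459, -2.80 ± 0.40). LOC111248074 was uneven in ATH-S, at 8.68, 78.46, 118.31 and 1.87 CPM in replicates 1 to 4. ATH-S replicate 4 thus lay just above the AN-CR libraries (0.42 to 1.7 CPM).

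**Figure D3:**
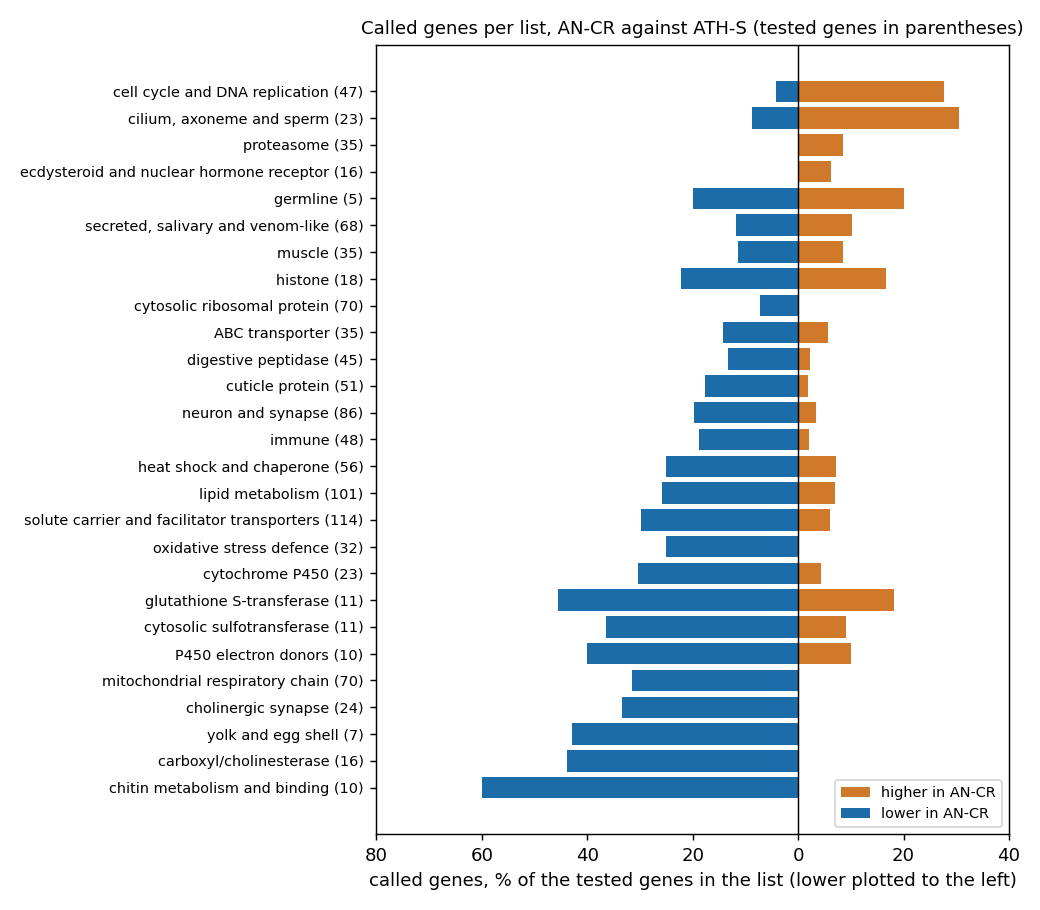
Called genes per list in AN-CR against ATH-S, as a percent of the tested genes in each of 27 lists, with higher genes to the right and lower genes to the left of 0. Cell cycle and DNA replication (13 of 47 higher) and cilium, axoneme and sperm (7 of 23 higher) lie furthest to the right, and chitin metabolism and binding (6 of 10 lower) furthest to the left.

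The comparison of tAN-CR with AN-CR asks what changes in resistant mites that are alive after contact with coumaphos. The clearest rise was in mitochondrially encoded cytochrome c oxidase subunit II (COX2), at 350 ± 48.6 CPM in AN-CR and 1513 ± 371 CPM in tAN-CR (SD, n = 4 each; log2 fold change 2.11 ± 0.17, edgeR adjusted p = 0.000156). Cytochrome b (CYTB) rose from 1399 ± 120 to 2847 ± 343 CPM (1.03 ± 0.13, adjusted p = 0.00879) and cytochrome c oxidase subunit I (COX1) from 1058 ± 134 to 2089 ± 206 CPM (0.98 ± 0.13, adjusted p = 0.0175). These genes encode parts of the respiratory chain. Mannose-P-dolichol utilization defect 1 protein-like (LOC111247401), of protein glycosylation, rose from 136 ± 7.53 to 222 ± 30.6 CPM (0.71 ± 0.10, adjusted p = 0.0272). COX2 was called in all 8 fits that left out 1 library. CYTB lost its call without AN-CR replicate 2, 3 or 4 (adjusted p up to 0.0826), and COX1 without these or tAN-CR replicate 1, 3 or 4 (up to 0.143). LOC111247401 kept its call only without tAN-CR replicate 2 (up to 0.204), and without the mitochondrial genes it kept its log2 fold change of 0.71 but had an adjusted p of 0.106. The adjustment then no longer counted 3 lower p-values.

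These 4 of 9272 genes were all that edgeR called, with 0 lower, while 945 genes (10.2%) had an unadjusted p under 0.05. Limma-voom called 4 genes and DESeq2 141, of which 114 were higher and 27 lower. In simulated data of this comparison edgeR recovered 13.4% of genes changed by 0.5 on the log2 scale, 74.6% of those changed by 1 and 100% of those changed by 2, among 9227 genes. Of the calls in these simulated data 5.3% were wrong for edgeR and 15.7% for DESeq2. The simulated genes varied independently, so these rates may not carry over to the real calls. Tumor protein 63-like (LOC111245928), next by p, did not pass (0.78 ± 0.13, adjusted p = 0.0619). Exposure and survival go together here, since dead mites were not collected.

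The 13 mitochondrial genes did not move as a block. Their log2 fold changes in tAN-CR were positive for 8 and negative for 5, from 2.11 for COX2 to -1.04 ± 0.35 for ATP8 (not called). ATP6 stood at 0.78 ± 0.14 (edgeR adjusted p = 0.0898). COX2 lies at positions 2734 to 3409 of the mitochondrial sequence NC_004454.2, on the plus strand. CYTB (9771 to 10874, plus strand) shares its last bases with ND1 on the minus strand, so reads there may be counted for either.

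**Figure D4:**
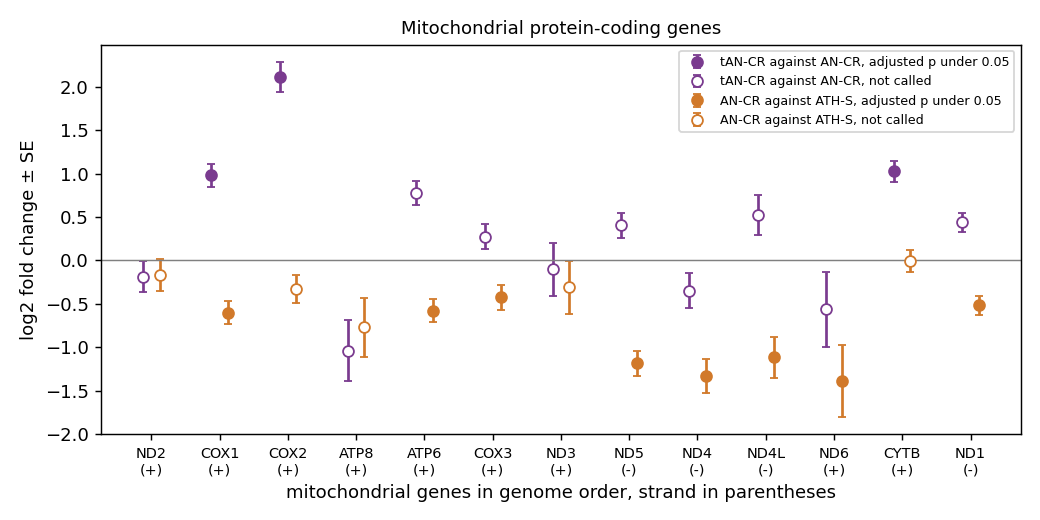
Log2 fold change ± SE of the 13 mitochondrial protein-coding genes in genome order, for tAN-CR against AN-CR and for AN-CR against ATH-S, with filled dots for an edgeR adjusted p under 0.05. In tAN-CR the changes run from 2.11 for COX2 to -1.04 for ATP8. In AN-CR 8 genes are called lower than in ATH-S, of which COX3 and ND6 lose the call in some fits that leave out 1 library.

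Most nuclear genes of the respiratory chain did not follow the risers. Over the whole list of 70 genes (65 nuclear and 5 mitochondrial, without CYTB and the ND genes) 2 rose and 0 fell, against 5 and 7 adjusted over the list alone and 4 and 9 by DESeq2, and 23 had an unadjusted p under 0.05. The median log2 fold change was -0.14 and the list was lower as a set (camera adjusted p = 2.44e-05; adjusted p = 0.922 with an estimated correlation). Its 65 nuclear genes had a median of -0.14, and 53 were negative. Of the 4 genes that DESeq2 called higher 3 were mitochondrial. The other was a nuclear gene of cytochrome c oxidase assembly (log2 fold change 0.76, DESeq2 adjusted p = 0.0125). Camera also placed lower the cytosolic ribosomal proteins (median -0.25, all 70 negative; adjusted p = 1.76e-20; adjusted p = 0.922 with an estimated correlation) and the cuticle proteins (median -0.37; adjusted p = 0.000294; adjusted p = 0.922 with an estimated correlation). Muscle genes (median -0.24; camera adjusted p = 0.000443; adjusted p = 0.922 with an estimated correlation) and proteasome genes (median -0.08; camera adjusted p = 0.00291; adjusted p = 0.922 with an estimated correlation) were also lower. The proteasome call was lost without tAN-CR replicate 3 (0.0912) or AN-CR replicate 3 (0.36) or 4 (0.0777). In the 4 lists besides the respiratory chain, edgeR called 0 genes, also over the list alone, with 37 ribosomal, 2 cuticle, 10 muscle and 4 proteasome genes at an unadjusted p under 0.05. DESeq2 called 1 ribosomal gene and none of the others.

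Detoxification genes did not pass in this comparison. None of the 23 cytochrome P450 genes was called by edgeR or DESeq2, over all genes or over the list alone, and 0 had an unadjusted p under 0.05. The 3 with the lowest p were probable cytochrome P450 49a1 (LOC111246534, 0.37 ± 0.27), 4V2-like LOC111243321 (0.16 ± 0.11) and probable cytochrome P450 12a5 (LOC111247492, 0.71 ± 0.48). NADPH--cytochrome P450 reductase-like stood at 307 ± 43.9 CPM after exposure (-0.22 ± 0.20). EdgeR and DESeq2 called 0 of 11 acetylcholinesterase genes, whose log2 fold changes ran from -0.57 (LOC111247592) to 0.18 (LOC111246636), with 1 at an unadjusted p under 0.05. For glutathione S-transferases, carboxyl/cholinesterases and ABC transporters both tools also called 0 genes, with 1, 1 and 3 at an unadjusted p under 0.05. Adjusted over the list alone, 1 gene of the P450 electron donor list, 2 lipid metabolism genes and 2 secreted genes rose, while edgeR called 0 of each over all genes. In these lists 1, 10 and 6 genes had an unadjusted p under 0.05, and DESeq2 called 1, 2 and 2. Its call in the electron donor list was cytochrome b561-like (LOC111251541, 0.513, DESeq2 adjusted p = 0.0356), which lies outside the P450 system.

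The comparison of tAN-CR with ATH-S joins population and exposure. Cytochrome P450 4V2-like (LOC111248731) was at 99.7 ± 12.3 CPM in tAN-CR against 404 ± 134 CPM in ATH-S (SD, n = 4 each; -2.02 ± 0.20, edgeR adjusted p = 7.39e-05). Chymotrypsin-like protease CTRL-1 (LOC111252338) fell from 17.3 ± 5.16 to 1.31 ± 0.143 CPM (-3.72 ± 0.37) and neuropeptide-like protein 31 (LOC111255289) from 33.0 ± 10.97 to 3.98 ± 0.83 CPM (-3.06 ± 0.26). Venom protease-like (LOC111254963) rose to 14.7 ± 1.79 CPM (2.51 ± 0.37) and COX2 from 440 ± 49.0 to 1513 ± 371 CPM (1.78 ± 0.17). Of 11 acetylcholinesterase genes 1 rose and 6 fell.

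EdgeR called 3760 genes (40.6%), 1985 higher and 1775 lower, with 270 and 547 of them at least 2-fold. The groups did not overlap for 38.6% of genes, against 2.86% by chance. Upper-quartile scaling gave 1614 higher and 2078 lower, so that the higher genes made up 43.7% of the calls against 52.8%. Leaving out 1 library gave between 2958 and 3838 calls.

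The acetylcholinesterases that fell were LOC111254737 (-1.52 ± 0.23), LOC111248568 (-1.47 ± 0.21), LOC111251676 (-1.37 ± 0.28), LOC111244098 (-1.11 ± 0.26), LOC111247592 (-0.64 ± 0.17) and LOC111247698 (-0.35 ± 0.11). LOC111243720 rose (0.62 ± 0.23, edgeR adjusted p = 0.0462), a call that held only without ATH-S replicate 2 and was lost in the other 7 fits (adjusted p up to 0.151). That of LOC111247698 was lost without tAN-CR replicate 4 (0.0557). Not called were LOC111246636 (-0.12), LOC111251379 (0.43), LOC111251954 (0.18) and LOC111252992 (0.50). Without tAN-CR replicate 2 LOC111251379 stood at -1.04, and without ATH-S replicate 4 LOC111246636 stood at 0.08. Cytochrome P450 4C1-like (LOC111244152) fell from 386 ± 91.1 to 198 ± 32.1 CPM (-0.97 ± 0.16).

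Of 70 cytosolic ribosomal protein genes 0 rose and 62 fell (0 and 67 adjusted over the list alone; DESeq2 called 68 and 67 had an unadjusted p under 0.05), with a median of -0.42 (camera adjusted p = 1.09e-16; adjusted p = 0.418 with an estimated correlation). In the respiratory chain 4 rose and 44 fell (4 and 47 adjusted over the list alone; camera adjusted p = 8.25e-09; adjusted p = 0.411 with an estimated correlation). Cell cycle and DNA replication was again the 1 list that camera placed higher, with 24 of 47 genes risen and 2 fallen (29 and 2 adjusted over the list alone). Its camera adjusted p was 0.000355, and 0.486 with an estimated correlation. Fry also placed it higher (adjusted p = 0.0433), with cilium, axoneme and sperm (6.02e-05) and hormone receptor (0.0256). In the cuticle list 0 of 51 rose and 14 fell (0 and 12 adjusted over the list alone, 16 called by DESeq2 and 18 at an unadjusted p under 0.05; camera adjusted p = 0.00181; adjusted p = 0.486 with an estimated correlation). In all, camera called 14 lists, 1 higher and 13 lower, and 0 with an estimated correlation, while fry, which tests a list on its own, called 18. The other lists called were carboxyl/cholinesterase (adjusted p = 0.411 with an estimated correlation), cholinergic synapse (0.411), cytochrome P450 (0.411), chitin and digestive peptidase (0.123 each), immune and lipid metabolism (0.426 each), solute carriers (0.438), muscle and neuron and synapse (0.486 each). The lipid call was lost without tAN-CR replicate 2 (0.0635) or ATH-S replicate 4 (0.0718). Fry did not call the cuticle (adjusted p = 0.0681), muscle (0.0614) and neuron and synapse (0.0568) lists, which camera called.

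Among genes outside the lists, uncharacterized LOC111248108 fell from 22.4 ± 8.45 to 2.42 ± 0.570 CPM (-3.22 ± 0.32) and LOC111245898 stood at 5962 ± 5424 and 753 ± 68.4 CPM (-2.98 ± 0.51, and -2.19 without ATH-S replicate 4). In ATH-S replicates 1 to 4 LOC111245898 stood at 5515, 3129, 1493 and 13711 CPM, in the same order as heat shock protein 83-like. The mRNA decay activator protein ZFP36L2-A-like (LOC111254151) rose from 72.0 ± 38.8 to 360 ± 127 CPM (2.31 ± 0.65, edgeR adjusted p = 0.0157).

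Of the 2299 genes that differed between AN-CR and ATH-S, 2027 (88.2%) were also called between tAN-CR and ATH-S, 965 higher and 1062 lower; 1 further gene was called in both comparisons in opposite directions. Independent lists would share 239.3 and 226.1 genes, a value that leaves out the shared ATH-S libraries. Simulated unchanged groups with shared ATH-S libraries shared 0, a value that leaves out all effects and so sets no scale for the excess. With the ATH-S libraries split so that each comparison had its own 2, the shared genes were fewest in a split with 458 and 3281 calls (440 shared, 80.9 for independent lists). They were most numerous in a split with 2463 and 2824 calls (1336 shared, 372.2 for independent lists). Across genes the log2 fold changes for population and for exposure had a Pearson r of 0.036 (Spearman 0.22), where simulated unchanged groups on the shared AN-CR libraries gave -0.481. The covariance was 0.006 against -0.0314 in the simulation, a difference of 0.0374. The simulated genes varied independently, without states shared by the genes of a library, so both simulated values may not hold for the real libraries. With the AN-CR libraries split between the comparisons, 2 and 2, r was 0.168 on average and ran from -0.1 to 0.414, so its sign depended on the split; genes are not independent replicates.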

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

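The 7 tests of the chaperone, cytochrome P450 and mitochondrial patterns were chosen after the result was seen, and the 3 tests on other splits of the libraries before.

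In each comparison 1 of 35 splits, the real one, gave as many calls, a share of 0.0286, the smallest that 35 splits allow. For AN-CR against ATH-S the real split called 2299 genes and the highest other 1482, with ATH-S replicates 1, 3 and 4 and AN-CR replicate 1 on 1 side. For tAN-CR against AN-CR the numbers were 4 and 0, and for tAN-CR against ATH-S 3760 and 2. In the 2 comparisons with ATH-S the real split thus had the most calls, which argues against chance without excluding it. The other splits mix the groups, so a real difference counts there as spread and lowers the calls. For tAN-CR against AN-CR the same share rests on the 4 calls alone, set against 0 in all 34 other splits, and does not exclude chance. These calls fell to 1 without AN-CR replicate 2, 3 or 4, to 2 without tAN-CR replicate 1, 3 or 4 and to 1 with the replicate block. By genes with an unadjusted p under 0.05 the real split (945) was not the highest there. Exchanging AN-CR replicate 3 with tAN-CR replicate 3 gave 1840, and AN-CR replicates 1 and 4 with tAN-CR replicates 1 and 3 on 1 side gave 1032. By that count exposure was thus not the strongest division of these libraries, while in the other 2 comparisons the real split was the highest (3721 and 4655).

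Of 56 chaperone genes 14 were lower in AN-CR and 4 higher, with uneven levels in ATH-S. Low depth is argued against, as 15 were called lower when all were tested again without the shallowest library, ATH-S replicate 1. For the other tests 1 library of each group was held out, and genes called lower without both were read in them, in 16 pairs. Scaling by a few abundant genes would move all genes of a library alike. For ATH-S replicates 1, 2 and 4 it is argued against as the whole cause. There the chosen genes differed by at least 0.354 more than the median of all genes (p up to 0.005 against random genes). For ATH-S replicate 3 it cannot be told apart from a change in these genes, at 0.108 in the lowest pair (p up to 0.28). A difference present in every ATH-S library stays open too, since the lowest of the 16 differences was 0.028, for replicate 3 against AN-CR replicate 3. Colony, handling and resistance stay open, as each phenotype comes from 1 colony.

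The fall of cytochrome P450 4V2-like (LOC111248731) in AN-CR is argued not to follow the chaperone state alone, because it was -1.492 ± 0.24 with heat shock protein 83-like as a covariate (edgeR adjusted p = 0.00984). The chaperone covariate kept 16.66% of the population's calls. The SE was 1.53 times as wide in the median over all genes. The fold change was 0.922 times as large in the median over the population's calls. What ended each call was not tested. Heat shock protein 83-like did not overlap between the groups (3480 to 25930 CPM in ATH-S, 2135 to 3325 CPM in AN-CR), so this fit separates its level from the group only in part. Colony ancestry and resistance stay open and untested.

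The share of mitochondrial counts was higher in tAN-CR, where COX2, CYTB and COX1 were called higher and 5 of the 13 changes were negative. An equal rise of all mitochondrial RNA is argued against, since the 13 changes spread around their mean by an SD of 0.83. The exact permutation p was 0.0286 over 70 assignments, the smallest they can give. Unequal rises of every kind would also give such a spread, so the test cannot decide on them. None of the 5 negative changes was called by edgeR, and DESeq2 called 5 mitochondrial genes higher and 0 lower. A single exposed library is argued against, as the lowest tAN-CR share exceeded the highest AN-CR share by 0.334% of counts, where the AN-CR libraries had an SD of 0.050%. COX2 was 1.94 to 2.21 over all 8 fits, with an edgeR adjusted p of at most 0.00225. Exposure, survival, and RNA handling or polyA selection that differed between groups stay open and untested.

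Single libraries lay far from the other 3 of their group in 22 of 336 groups of values, where chance gives about 16.8, or 1 in 20. ATH-S replicate 4 accounts for 7 of them. Its 10 most abundant genes held 16.533% of counts (others 11.108% to 11.704%). In CPM it had 405.65 for cytochrome P450 4c3-like LOC111246554 (184.68 to 205.45) and 171.17 for glutathione S-transferase LOC111244895 (108.17 to 115.19). It had 649.11 for sulfotransferase LOC111247389 (306.47 to 335.65) and 860.23 for cathepsin LOC111244088 (504.32 to 522.68). It had 170.8 for glutathione peroxidase-like LOC111243815 (80.42 to 92.45) and 277.92 for ATP6 (239.91 to 244.53).

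ATH-S replicate 1 had 5.96 CPM for venom protease-like LOC111254963 (1.37 to 2.08) and ATH-S replicate 3 had 119.75 CPM for solute carrier LOC111250761 (134.34 to 136.24). AN-CR replicate 1 had 34.37 CPM for acetylcholinesterase LOC111248568 (23.96 to 25.69) and 34.78 CPM for vitellogenin-3-like LOC111248912 (96.78 to 100.15). AN-CR replicate 2 had 0 CPM for LOC111249382 (0.67 to 0.76) and AN-CR replicate 3 had 0.085 CPM for LOC111243808 (0 in the others). In tAN-CR replicate 2, LOC111248074 stood at 7.07 CPM (0.64 to 1.23), acetylcholinesterase LOC111251379 at 12.87 CPM (0.7 to 2.65) and LOC111249888 at 185.17 CPM (163.19 to 166.3). In tAN-CR replicate 3, NADPH--cytochrome P450 reductase LOC111252141 stood at 372.8 CPM (279.91 to 293.21) and acetylcholinesterase LOC111252992 at 41.9 CPM (28.23 to 29.38). In tAN-CR replicate 4, mitochondrial genes held 1.0496% of counts (0.87661% to 0.89512%). It had 81.74 CPM for LOC111244793 (49.48 to 54.91), 110.35 CPM for glutathione S-transferase LOC111246365 (83.24 to 87.48) and 86.9 CPM for chitinase LOC111250845 (117.96 to 123.33).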

How the results depend on the processing

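The fits with a covariate, without extreme libraries or without mitochondrial genes were chosen after the data were seen. Among the single genes and lists over all alternatives, 5473 values kept their direction and side of the threshold, 611 lost the threshold, 16 gained it and 26 changed sign.

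For AN-CR against ATH-S the count was 1359 to 2717 when 1 library was left out, with the lowest without AN-CR replicate 2, against 2299. It was 1542 with only the compared groups in the fit. It was 440 with the heat shock protein 83-like covariate, where errors were wider. Of the 129 genes called under the naming rule, 129 kept their call with DESeq2, 117 with limma-voom and 40 with that covariate. Acetylcholinesterase LOC111247592 changed sign without AN-CR replicate 2 (0.01, and -0.167 to 0.01 over the fits without 1 library), without the high heat shock protein 83-like libraries (0.041) and with that covariate (0.129). LOC111251954 was -0.06 without AN-CR replicate 1 (-0.06 to 0.394 over such fits). With the covariate LOC111243059 was 0.245 and LOC111246636 was 0.174.

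For tAN-CR against AN-CR DESeq2 called 141 genes against 4 by edgeR, the vitellogenin covariate gave 14, and leaving out 1 library gave 1 to 5. Leaving out the mitochondrial genes gave 0 by edgeR, with 938 genes at an unadjusted p under 0.05. Of the 4 genes 3 are mitochondrial, and the adjusted p of LOC111247401 then rose to 0.106. The sign of LOC111251954 changed with limma-voom (0.03), the replicate block (0.02), 3 fits without 1 library (-0.214 to 0.211 over all), without the low-vitellogenin libraries (0.211) and with the vitellogenin covariate (0.073). LOC111252992 changed sign without tAN-CR replicate 3 (-0.083) or AN-CR replicate 3 (-0.048), in a range up to 0.199. LOC111243720 did so without tAN-CR replicate 4 (-0.049) or AN-CR replicate 1 (-0.108), in a range up to 0.164, without the low-vitellogenin libraries (-0.109) and with the vitellogenin covariate (-0.055). LOC111244098 was 0.009 without tAN-CR replicate 4 (range -0.287 to 0.009). LOC111248568 was 0.019 without AN-CR replicate 1 (range -0.177 to 0.019) and without the low-vitellogenin libraries.

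For tAN-CR against ATH-S counts stayed within 2958 and 3838 when 1 library was left out. LOC111251379 was -0.249 with limma-voom and -1.041 without tAN-CR replicate 2 (range up to 0.795). LOC111246636 was 0.084 without ATH-S replicate 4 (range from -0.227) and 0.085 without the low-vitellogenin libraries. With an estimated correlation camera called 0 lists in each of the 3 comparisons, against 14, 5 and 14 with the preset one. Fry called 15, 0 and 18. In AN-CR against ATH-S fry did not call the cell cycle (adjusted p = 0.104), ribosomal (0.0967) and neuron (0.102) lists, which camera called. The correlation of population and exposure changes was -0.1 to 0.414 over splits of AN-CR, against 0.036. Except where a sentence gives a reason, the cause was not tested.

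Replicate numbers are not stated to pair libraries. Same-numbered AN-CR and ATH-S libraries had deviations correlated at 0.344, 0.194, 0.226 and -0.14. Numbers were to be taken as pairs only where each of these was over 0.1, and 1 of the 4 was not. With the replicate block the counts were 1827, 1 and 3410, and 3 of 8, 0 of 8 and 0 of 8 libraries correlated best with their own number. In AN-CR against ATH-S 21 of the 129 calls then ended. Of the genes named in the text these were LOC111252141 (edgeR adjusted p = 0.0524), LOC111248912 (0.052), LOC111248841 (0.0532) and LOC111254725 (0.0508). In tAN-CR against AN-CR the calls of CYTB (0.063), COX1 (0.163) and LOC111247401 (0.194) ended, and in tAN-CR against ATH-S those of LOC111243720 (0.0552) and LOC111248912 (0.0831).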

Other observations

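The test of neighbouring genes and the genes named here were chosen after the result was seen. Uncharacterized gene LOC111243808 had 8, 36, 19 and 13 counts in ATH-S replicates 1 to 4, which is 1.62 to 3.40 CPM. It had 0, 0, 1 and 0 counts in AN-CR and 0, 1, 1 and 0 in tAN-CR, all under a floor of 3 counts per library. LOC111255640 ranged from 1.25 to 2003 CPM within ATH-S, and stood at 5.31 CPM in tAN-CR replicate 4.

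Of the 412 genes that fell at least 2-fold in AN-CR, 39 adjacent pairs lay side by side, against a median of 18 and a maximum of 34 over 10000 reshufflings of gene order (permutation p = 1e-04, the smallest these can give). Without the pairs ND5 and ND4, ND4 and ND4L, and ND4L and ND6, left out because the first 8 letters of their product names match (a rule not applied to uncharacterized genes), 36 pairs remained, against a median of 18 (permutation p = 1e-04, also the smallest), and 22 of them had an uncharacterized member.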
